A study of Arabidopsis thaliana with 8 samples.

How the data were processed

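Gene expression was measured in vegetative shoot apices of Arabidopsis thaliana grown for 20 days in short days. There were 4 genotypes with 2 arrays each: the wild-type accession Col-0, the hypomorphic alleles se-1 of SERRATE (SE) and ago1-27 of ARGONAUTE1 (AGO1), and se-1 carrying p35S::MIR156, a transgene that expresses a miR156 precursor from the viral 35S promoter. Per the labels, total RNA was extracted with a Qiagen plant kit, amplified and biotin-labelled in a single round with an Ambion kit, and hybridized to Affymetrix ATH1 arrays, 1 array per sample. Groups were taken from the genotype labels. The labels do not say that the replicates came from separate plants, so p-values measure only the spread between these samples.

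The deposited values are linear probe set signals (intensity), and the submitters' notes name GCOS, with no version and no signal algorithm. The authors scaled each array: the 2% trimmed mean over all 22810 probe sets was 200.02 on each of the 8 arrays. The values carry no detection calls, and the precision is limited by the number of arrays. Median signals were between 76.6 and 82.4. The 27 bacterial control probe sets, which match no plant transcript, gave the background: the highest of them was between 14.2 and 34.1 per array, and 65.1% to 74.2% of probe sets lay above it. Where all arrays of a genotype lay within that range, a fold is given as at least the ratio of 2 geometric means, that of the other genotype's signals over that of the highest bacterial signal on each array within background. Where only 1 of the 2 arrays did, the fitted value is given, and it depends on the pseudocount.

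The 64 control probe sets were left out, signals were transformed as log2(signal + 16) with no further normalization, and the lowest 30% of probe sets by mean over all arrays were left out, so that 15922 of 22746 were tested. A linear model with 1 mean per genotype was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with 4 residual and 11.27 prior degrees of freedom. There were 5 comparisons, and probe sets with a two-sided Benjamini-Hochberg adjusted p under 0.05 within a comparison are called changed. Log2 changes and their standard errors (SE of the fit) are from this model, so folds are moderated for dim probe sets, and signals are means with the SD of 2 arrays. Groups of 2 are too small for tests of outlying samples or of other splits. Sharing of arrays between comparisons was measured with 100 simulated draws in which no gene changed. The share of opposite signs and the overlap in these draws, over as many probe sets as were called, taken by p, were added after the data were seen.

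A probe set annotation table that lists 14016 probe sets gave gene names. It pairs 13513 with 1 gene and 503 with several. Of those gene identifiers, 13436 matched the reference gene table of assembly TAIR10.1 and 77 did not. In all, 8822 tested probe sets had 1 gene, covering 8735 genes, and 8730 probe sets other than controls are unlisted. AGO1 and the 11 SPL genes targeted by miR156 in the fixed list have no listed probe set and are not analysed here. Probe sets with the endings _s_at and _x_at can detect several related transcripts. The genes named were fixed by rule: in each comparison the 8 largest rises and 8 largest falls among called probe sets whose arrays did not overlap, up to 4 called members of each gene list, and SE in every comparison. At most 2 probe sets with no listed gene that rose and 2 that fell are described per comparison.

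The 24 gene lists hold 351 genes, of which 54 had a probe set paired with 1 gene and 46 were tested. The 9 lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01, 1 probe set per gene, adjusted over the 9. They were targets of other miRNAs (9 of 80 members tested), ta-siRNA and PPR targets (4 of 18), small RNA machinery (5 of 26) and flowering promoters (4 of 12). The others were leaf polarity (3 of 14), flavonoid and anthocyanin genes (4 of 17), ABA and cold response (3 of 15), auxin response (3 of 12) and photosynthesis (3 of 20). Counts of list genes in the results are of these tested members, which are a small part of each list. Camera with an estimated correlation and fry were alternatives. In addition, 21 families of at least 8 genes, formed from symbols and annotation, were tested after the data were seen. On data simulated for se-1 against Col-0 with 15922 probe sets, 200 of them changed and 10 draws, the procedure recovered 75.0% of 2-fold and 99.8% of 4-fold changes, with 7.18% false among the calls. The simulated noise was normal, independent between probe sets, and had the moderated spread of the fit. Deviations shared by many probe sets of an array were not simulated, so these rates may be too favourable for the real arrays.

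The genotype comparisons, the tests, the gene lists, the naming rule and the alternatives were chosen before the data were examined, except where the text says otherwise. The alternatives were a pseudocount of 1 or 64, no filter or the lowest 50% left out, quantile normalization, median centring, eBayes without a trend or robust, only the 2 genotypes compared in the fit, replicate number as a block, a 2-fold minimum, and leaving out each array in turn. Where an array is left out, the lone array of that genotype is assumed to vary like the other genotypes.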

Results

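Transcript levels were measured in vegetative shoot apices of 20-day-old short-day plants of 4 genotypes, with 2 arrays for each. SE is a zinc-finger protein that acts in microRNA processing, and AGO1 is the protein that carries microRNAs to their target transcripts. The line se-1 p35S::MIR156 carries a transgene for miR156, which represses SPL transcription factors and holds plants in the juvenile phase. The level of miR156 was not measured here. Replicate arrays correlated across probe sets with r of 0.978 in Col-0, 0.967 in ago1-27, 0.974 in se-1 and 0.980 in se-1 p35S::MIR156. These values are across genes, which are not independent replicates. The ratio of the 3' to the 5' actin control probe sets, a sign of RNA quality and labelling, was 4.83 and 4.40 on the ago1-27 arrays. It was 3.91 and 2.81 in Col-0, 2.97 and 4.22 in se-1, and 3.26 and 3.48 in se-1 p35S::MIR156.

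**Figure D1:**
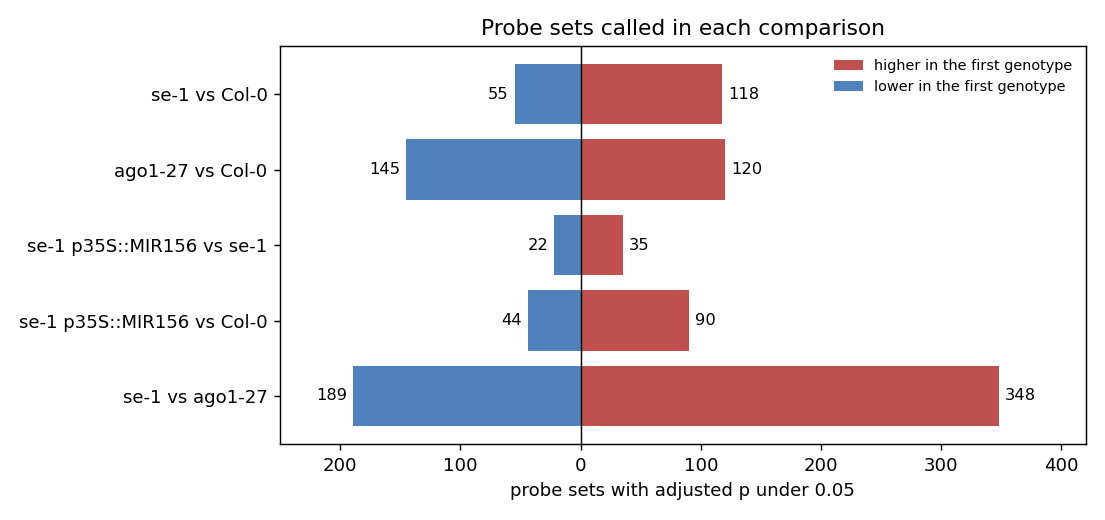
Number of probe sets with adjusted p under 0.05 in each of the 5 comparisons (horizontal axis), with bars to the right for probe sets higher in the first genotype and bars to the left for those lower. The comparison of se-1 with ago1-27 had the longest bars, 348 and 189, and that of se-1 p35S::MIR156 with se-1 the shortest, 35 and 22.

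The comparison of se-1 with Col-0 asks which transcripts depend on SE. The cytochrome P450 gene CYP71B22 rose by 2.22 on the log2 scale (SE 0.283), from a signal of 82.4 ± 32.1 to 455 ± 214 (SD, n = 2), with adjusted p = 0.00101. AT4G18280 rose from 272 ± 11.5 to 946 ± 11.1 (SD, n = 2). The chitinase family genes AT2G43590 and AT2G43620 rose as well, the first at least 3.24-fold from a Col-0 level within background and the second by 1.70 on the log2 scale. AT5G24240 was at least 4.43-fold higher than its Col-0 level, which was within background. The other large rises were those of AT1G13880 (log2 change 1.73), the subtilisin-like protease gene ATSBT5.2 (1.70) and AT3G53980 (1.67).

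In se-1, AT2G25510 fell from 903 ± 161 to 192 ± 15.1 (SD, n = 2), a log2 change of -2.14. ECS1 fell from 1030 ± 395 to 253 ± 1.77 (SD, n = 2) and AT5G48490 from 183 ± 35.9 to 33.1 ± 14.8 (SD, n = 2). Log2 changes were -1.86 for AT5G62360 and -1.77 for AT1G19960. They were -1.72 for AT1G31690 and -1.53 for AT1G14730. AT5G48490 and AT1G31690 had 1 se-1 array within background. PYK10, the beta-glucosidase of endoplasmic reticulum bodies and the only tested member of the root marker list, fell by 1.09 on the log2 scale, from 1663 ± 20.8 to 786 ± 208 (SD, n = 2). Among probe sets with no listed gene, the largest falls were at least 14.5-fold and at least 22.8-fold, to se-1 levels within background (from 341 ± 74.0 and 532 ± 34.6; SD, n = 2), and the largest rises were 1.90 and 1.79 on the log2 scale. The SE probe set itself gave 117 ± 0.0955 in se-1 and 132 ± 4.56 in Col-0 (SD, n = 2; log2 change -0.15, adjusted p = 0.839). The data do not show whether that probe set lies in the part of the gene changed in se-1.

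Of the 4 tested flavonoid and anthocyanin genes, of 17 in the list, 1 fell in se-1. UF3GT, a glycosyltransferase gene, went from 256 ± 55.9 to 67.2 ± 7.46 (SD, n = 2). The list had a mean log2 change of -0.66 (camera adjusted p = 0.00515), and 2 genes were called when adjusted over the list alone. With an estimated correlation its adjusted p was 0.232. Of the 3 ABA and cold response genes, COR15A, which encodes a chloroplast protein induced by cold, rose from 786 ± 176 to 1732 ± 441 (SD, n = 2; adjusted p = 0.0429). All 3 had positive values, with a list mean of 0.69 (adjusted p = 0.00515, and 0.213 with an estimated correlation), and 1 was called when adjusted over the list alone. The 3 leaf polarity genes YAB3, YAB5 and PHV had a mean of 0.48 (adjusted p = 0.0256, and 0.213 with an estimated correlation). Of these, 0 were called by limma over all genes or when adjusted over the list alone, and 2 had an unadjusted p under 0.05. The other 6 lists had adjusted p between 0.0568 and 0.903, and the auxin response list had a mean of 0.01 and a median of -0.23.

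Across all 15922 probe sets, 173 differed between se-1 and Col-0, 118 higher and 55 lower in se-1, of which 131 differed by at least 2-fold. The count was 32 without Col-0 replicate 1, 83 without Col-0 replicate 2, 89 without se-1 replicate 1 and also without se-1 replicate 2, and 68 with no filter on dim probe sets. Calls ended (adjusted p between 0.0525 and 0.423) for COR15A and PYK10 without Col-0 replicate 1, Col-0 replicate 2 or se-1 replicate 1, for AT2G43590 without Col-0 replicate 1 or se-1 replicate 1, for AT1G14730 and ATSBT5.2 without Col-0 replicate 1, and for ECS1 without Col-0 replicate 2. Those of COR15A and PYK10 also ended with pseudocount 1, no filter, eBayes without a trend or robust eBayes, and that of PYK10 with quantile normalization (adjusted p between 0.0512 and 0.192). The flavonoid and leaf polarity list calls ended without Col-0 replicate 2 (adjusted p = 0.103 and 0.131) and without se-1 replicate 2 (0.119 for each), and the flavonoid call with fry (0.132).

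The comparison of ago1-27 with Col-0 asks which transcripts depend on AGO1. PYK10 fell by 3.24 on the log2 scale (SE 0.247, adjusted p = 3.96e-06), from 1663 ± 20.8 to 167 ± 61.8 (SD, n = 2). The jacalin-related lectin genes JAL22 and JAL33 also fell, from 369 ± 38.1 to 57.7 ± 16.5 and from 320 ± 0.672 to 64 ± 7.49 (SD, n = 2). Of the other lectin genes of this name that were tested, both chosen after their values were seen, JAL34 fell by 1.73 on the log2 scale (adjusted p = 0.000160) and JAL23 had a log2 change of 0.51 (adjusted p = 0.398). Of 17 other root-abundant genes, listed after the data were seen, 3 were bright enough to be tested: mean signals in Col-0 and ago1-27 were 39.6 and 3.09 for AT1G62510 (called lower), 38.0 and 13.4 for AT1G49570 (not called) and 55.8 and 58.2 for HRGP1 (not called). AT5G59330 fell from 456 ± 37.0 and AT3G55920 from 292 ± 36.4 (SD, n = 2) to levels within background, at least 16.7-fold and 10.6-fold lower.

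Other falls in ago1-27 were those of AT4G11190 (log2 change -2.20) and AT3G02910 (-1.98), each with 1 ago1-27 array within background, and AT5G40020, which was at least 2.90-fold lower and within background. Among the rises, CYP71B22 went up to 589 ± 92.7 (SD, n = 2; log2 change 2.65, adjusted p = 0.000114). AT1G43590, annotated as a pseudogene, was at least 8.78-fold higher than a Col-0 level within background. AT5G03350 rose from 367 ± 129 to 1723 ± 212, and AT3G28500, a ribosomal P protein gene, from 214 ± 34.8 to 696 ± 60.8 (SD, n = 2). AT5G62210 rose by 1.78, AT1G07440 by 1.52 and the chloroplast gene ndhG, with 1 Col-0 array within background, by 1.63 on the log2 scale. The largest changes among probe sets with no listed gene were rises of 2.73 and 2.06 on the log2 scale and log2 changes of -2.95 and -2.59, and 3 of these 4 had 1 array within background. SE had a log2 change of 0.20 (adjusted p = 0.735).

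All 3 tested ABA and cold response genes, of 15 in the list, changed in ago1-27, in opposite directions. COR15B rose from 341 ± 68.1 to 1799 ± 1130 and COR15A from 786 ± 176 to 1975 ± 354, and the dehydrin gene COR47 fell from 1038 ± 15.8 to 572 ± 21.3 (SD, n = 2). The list mean was 0.89 (camera adjusted p = 0.147), with 3 called when adjusted over the list alone. The cytokinin-induced response regulator gene ARR15 fell from 545 ± 50.6 to 196 ± 21.3 (SD, n = 2; adjusted p = 0.00105). The 4 flavonoid genes all had negative values, with a mean of -0.61 (adjusted p = 0.00144, and 0.353 with an estimated correlation). Of these, 0 were called by limma over all genes, 3 when adjusted over the list alone, and 3 had an unadjusted p under 0.05. The photosynthesis genes LHCB4.1, RCA and PRK had a mean of 0.40 (adjusted p = 0.037, and 0.353 with an estimated correlation), with 0 called by limma over all genes, 1 when adjusted over the list alone and 2 with an unadjusted p under 0.05. The other 7 lists had adjusted p between 0.147 and 0.679, and the leaf polarity list had a mean of 0.08 and a median of -0.03. The ago1-27 arrays also had the highest 3' to 5' actin ratios.

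In all, 265 probe sets differed between ago1-27 and Col-0, 120 higher and 145 lower in ago1-27, and 202 of them by at least 2-fold. The count was 93 without Col-0 replicate 1, 81 without Col-0 replicate 2, 337 without ago1-27 replicate 1, 148 without ago1-27 replicate 2, and 98 with no filter. Calls ended (adjusted p between 0.0516 and 0.187) for COR47 without Col-0 replicate 1 or 2, for ndhG without Col-0 replicate 2 or ago1-27 replicate 2, for 1 of the probe sets with no listed gene, the rise of 2.06, without Col-0 replicate 2, and for AT5G62210 and COR15A without Col-0 replicate 1 or ago1-27 replicate 2. Those of ndhG, AT5G62210 and COR15A also ended with no filter, and that of COR15A with eBayes without a trend (adjusted p between 0.0502 and 0.110). The photosynthesis call ended without Col-0 replicate 1 (adjusted p = 0.187), Col-0 replicate 2 (0.0571) or ago1-27 replicate 2 (0.186), and the flavonoid call without Col-0 replicate 2 (0.0623) or ago1-27 replicate 1 (0.167). With fry both ended (0.113 and 0.141).

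The comparison of se-1 p35S::MIR156 with se-1 asks what added miR156 does in the se-1 background. Of the 4 flavonoid and anthocyanin genes, 3 rose with the transgene. DFR, the dihydroflavonol reductase gene, rose from 527 ± 155 to 1467 ± 344, UF3GT from 67.2 ± 7.46 to 218 ± 27.5, and the glycosyltransferase gene AT4G14090 from 212 ± 56.4 to 517 ± 35.3 (SD, n = 2). UGT78D2 had a log2 change of 0.86 (adjusted p = 0.0794). The list mean was 1.27 (camera adjusted p = 1.67e-12, and 0.121 with an estimated correlation), with 3 of 4 genes called over all genes and 4 when adjusted over the list alone.

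ECS1 rose from 253 ± 1.77 to 1128 ± 344, AT3G02910 from 137 ± 5.72 to 607 ± 75.7 and ZW9 from 75.5 ± 22.7 to 333 ± 39.6 (SD, n = 2). PYK10 rose from 786 ± 208 to 1941 ± 560 (SD, n = 2; adjusted p = 0.0356). The lectin genes JAL22, JAL33 and JAL34, chosen after their values were seen, rose by 1.11, 1.18 and 1.40 on the log2 scale, and JAL23 had a log2 change of -0.07 (adjusted p = 0.969). AT4G19380, with 1 se-1 array within background, rose by 1.82 and AT2G25510 by 1.76, and AT1G43590 and AT3G19550 were at least 2.85-fold and 3.05-fold higher than se-1 levels within background. Probe sets with no listed gene rose by up to 1.98 and 1.92, and 1 of these had 1 se-1 array within background.

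With the transgene CYP71B22 fell from 455 ± 214 to 58.7 ± 5.95 and AT3G28500 from 432 ± 19.0 to 104 ± 22.0 (SD, n = 2), log2 changes of -2.58 and -1.91. AGL42, a MADS-box gene that promotes flowering, fell from 136 ± 2.79 to 31.9 ± 5.98 (SD, n = 2; adjusted p = 0.0043). It was the only called gene of the 4 flowering promoters, whose mean was -0.63 (camera adjusted p = 0.0204, and 0.202 with an estimated correlation), with 2 called when adjusted over the list alone. COR15A fell from 1732 ± 441 to 729 ± 280 (SD, n = 2; adjusted p = 0.0436), and the thionin gene THI2.1 was at least 3.55-fold lower, within background. AT4G34400, AT2G43620 and AT5G49120 had log2 changes of -1.66, -1.31 and -1.26. Of the probe sets with no listed gene, the largest falls were a log2 change of -2.03 and a fall of at least 4.67-fold to within background. SE had a log2 change of 0.28 (adjusted p = 0.720). The other 7 lists had adjusted p between 0.0881 and 0.579.

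In this comparison 57 probe sets differed, 35 higher and 22 lower with the transgene, and 49 of them by at least 2-fold. The excess of rises was lost with no filter (7 higher and 8 lower) and with eBayes without a trend (12 and 13). It held under the other alternatives that left out no array of these 2 genotypes. The count was 41 without se-1 replicate 1, 25 without se-1 replicate 2, 19 without se-1 p35S::MIR156 replicate 1, 10 without its replicate 2, 15 with no filter and 25 with eBayes without a trend. Of 23 named probe sets, CYP71B22, AT3G28500, ZW9 and 3 with no listed gene were called without each array in turn and with no filter, which ended the other 17 calls. Those of COR15A, PYK10, AT4G14090, DFR and AT2G25510 ended with eBayes without a trend, those of COR15A, PYK10, AT4G14090, AT1G43590 and 1 with no listed gene with pseudocount 1, those of COR15A, THI2.1 and AT5G49120 with only these 2 genotypes in the fit, that of COR15A with robust eBayes and that of THI2.1 with pseudocount 64 (adjusted p between 0.0523 and 0.288). Calls ended for 5 without se-1 replicate 1 (AT3G19550, COR15A, PYK10, THI2.1 and 1 with no listed gene), and for 11 without se-1 replicate 2, among them DFR, UF3GT and AT4G14090. They ended for 14 without se-1 p35S::MIR156 replicate 1, among them ECS1, UF3GT and PYK10, and for 15 without its replicate 2, among them AGL42, DFR and PYK10, with adjusted p between 0.0502 and 0.460 over the 4 arrays. The flowering promoter call ended without se-1 replicate 2 (adjusted p = 0.106), with no filter (0.0536) and with the lowest 50% left out (0.171).

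**Figure D2:**
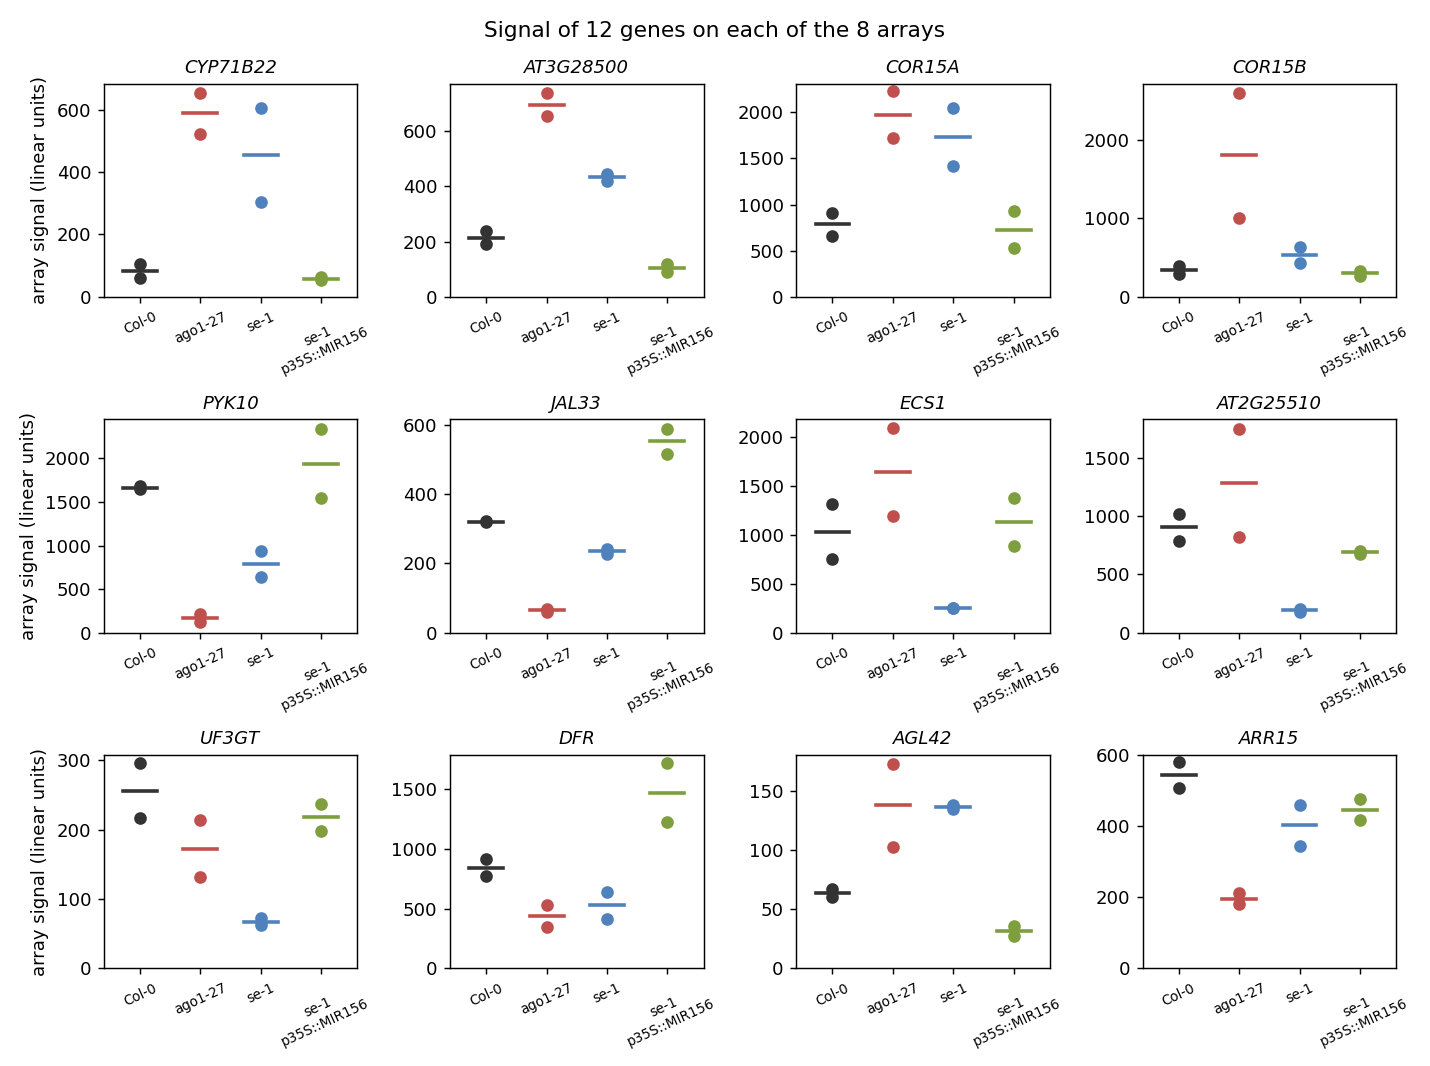
Array signal (vertical axes, linear intensity from 0) of 12 named genes on each of the 8 arrays by genotype (horizontal axes), with points for arrays and lines for the mean of 2. CYP71B22 had means of 82.4, 589, 455 and 58.7 in Col-0, ago1-27, se-1 and se-1 p35S::MIR156.

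The comparison of se-1 p35S::MIR156 with Col-0 shows what differed from wild type with the lesion and the transgene together. GH9B13, a glycosyl hydrolase gene, fell from 1513 ± 36.4 to 417 ± 70.0, AT1G10640 from 415 ± 35.3 to 111 ± 1.94 and AT1G19960 from 520 ± 78.9 to 110 ± 47.3 (SD, n = 2). AT1G13880 rose from 171 ± 10.6 to 526 ± 17.1 (SD, n = 2), and AT5G24240 was at least 3.15-fold and AT1G43590 at least 3.17-fold higher than Col-0 levels within background. AT3G62960, AT2G32150, AT3G02910, AT5G52790 and AT1G26730 rose by 1.81, 1.80, 1.72, 1.54 and 1.33 on the log2 scale. The remaining large falls were those of AT5G48490 (-1.50), AT1G64370 (-1.49), AT1G30515 (-1.47), AT5G59305 (-1.40) and AT5G62360 (-1.38). Of these genes, AT3G62960 and AT5G52790 had 1 Col-0 array within background, and AT5G59305 1 array of se-1 p35S::MIR156. The same pair of probe sets with no listed gene that fell furthest in se-1 fell here too, the brighter from 532 ± 34.6 to 11.9 ± 13.6 (SD, n = 2), with 1 of the 2 arrays within background, and the other by at least 20.9-fold. The largest rises among probe sets with no listed gene were 2.75 and 2.20. SE had a log2 change of 0.13 (adjusted p = 0.927).

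The flavonoid genes had a mean log2 change of 0.61 (camera adjusted p = 0.00074, and 0.262 with an estimated correlation). UGT78D2 rose from 304 ± 31.9 to 590 ± 89.1 (SD, n = 2), and 3 of the 4 were called when adjusted over the list alone. COR47 rose from 1038 ± 15.8 to 1782 ± 187 (SD, n = 2; adjusted p = 0.0287). Of the 9 targets of other miRNAs, 8 had positive values, with a mean of 0.38 (adjusted p = 0.000879, and 0.162 with an estimated correlation), and 0 were called by limma over all genes or when adjusted over the list alone, with 4 at an unadjusted p under 0.05. The 4 ta-siRNA and PPR targets, all pentatricopeptide repeat genes, had a mean of 0.47 (adjusted p = 0.00936, and 0.180 with an estimated correlation), with 0 called by limma over all genes, 2 when adjusted over the list alone and 2 at an unadjusted p under 0.05. The other 6 lists had adjusted p between 0.260 and 0.713. In the ABA and cold list the mean was 0.15 and the median -0.14.

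Between se-1 p35S::MIR156 and Col-0, 134 probe sets differed, 90 higher and 44 lower, and 107 of them by at least 2-fold. The count was 14 without Col-0 replicate 1, 42 without Col-0 replicate 2, 26 and 22 without replicates 1 and 2 of se-1 p35S::MIR156, 28 with no filter, 75 with eBayes without a trend and 280 with only these 2 genotypes in the fit. Of 22 named probe sets, AT1G10640, AT1G13880, AT1G19960, GH9B13 and 4 with no listed gene were called without each array in turn and with no filter, which ended the other 14 calls. Those of UGT78D2, COR47, AT1G43590 and AT5G59305 ended with eBayes without a trend, that of AT1G43590 also with pseudocount 1 and that of AT5G59305 with pseudocount 64 or quantile normalization (adjusted p of up to 0.360). The flavonoid list call ended with fry (adjusted p = 0.175) and that of the ta-siRNA and PPR targets with no filter (0.0755). Calls ended for 13 without Col-0 replicate 1, 11 without Col-0 replicate 2, 12 without se-1 p35S::MIR156 replicate 1 and 11 without its replicate 2 (adjusted p between 0.0654 and 0.451). UGT78D2, COR47, AT1G26730, AT1G43590, AT3G02910, AT5G24240, AT5G52790 and AT5G59305 lost their calls in each case.

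The comparison of se-1 with ago1-27 tests whether the changes of the mutants differ. AT3G55920 and AT5G59330 were at least 9.99-fold and 7.62-fold higher in se-1. The serine carboxypeptidase-like gene scpl31 was 926 ± 259 in se-1 and 162 ± 12.4 in ago1-27, PYK10 was 786 ± 208 and 167 ± 61.8, and AT4G18280 was 946 ± 11.1 and 220 ± 5.27 (SD, n = 2). Log2 changes were 2.24 for AT4G36430, which had 1 ago1-27 array within background, 2.09 for ATSBT5.2 and 1.89 for AT1G19530. AT1G43590 was at least 7.90-fold lower in se-1. AT1G19960 was 144 ± 46.7 in se-1 and 1310 ± 44.3 in ago1-27, AT5G48490 was 33.1 ± 14.8 and 394 ± 51.3, and AT5G03350 was 238 ± 45.9 and 1723 ± 212 (SD, n = 2). ECS1, AT2G25510, AT5G62360 and AT1G31690 had log2 changes of -2.56, -2.55, -2.54 and -1.97, and AT5G48490 and AT1G31690 had 1 se-1 array within background. Of the probe sets with no listed gene, 1 was 6.25-fold higher in se-1 and another at least 5.26-fold higher, and the pair at background in se-1 were at least 35.5-fold and 13.3-fold lower than in ago1-27.

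Of the targets of other miRNAs, the F-box gene LCR was 469 ± 46.7 in se-1 and 266 ± 30.7 in ago1-27, and ARPN was 1809 ± 142 and 1113 ± 6.87 (SD, n = 2). These 2 of the 9 were called, and 5 when adjusted over the list alone (list mean 0.22, camera adjusted p = 0.179). COR47 and ARR15 were higher in se-1 by 1.19 and 0.97 on the log2 scale, and COR15B and UF3GT had log2 changes of -1.60 and -1.15. The photosynthesis genes had a mean of -0.49 (adjusted p = 0.0188, and 0.390 with an estimated correlation), with 0 called by limma over all genes, 3 when adjusted over the list alone and 3 at an unadjusted p under 0.05. The other 8 lists had adjusted p between 0.179 and 0.921, with means and medians of opposite sign for small RNA machinery (-0.04 and 0.08) and flavonoid genes (-0.04 and 0.30). For ABA and cold response the mean was -0.20 while the camera statistic pointed up. SE had a log2 change of -0.36 (adjusted p = 0.402).

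In all, 537 probe sets differed between se-1 and ago1-27, 348 higher and 189 lower in se-1, and 304 of them by at least 2-fold. The count was 342 without ago1-27 replicate 2, 265 without se-1 replicate 1, 257 without se-1 replicate 2, 249 with no filter and 263 with only these 2 genotypes in the fit. Calls ended (adjusted p between 0.0597 and 0.317) for ARPN without any 1 of the 4 arrays, for LCR without ago1-27 replicate 1, se-1 replicate 1 or se-1 replicate 2, for COR15B without ago1-27 replicate 1 or se-1 replicate 2, and for ARR15, AT1G19530 and UF3GT without ago1-27 replicate 2 or se-1 replicate 2. Those of ARPN and AT1G19530 also ended with no filter and with eBayes without a trend, those of UF3GT and COR15B with no filter, that of LCR with eBayes without a trend, those of LCR and ARPN with only these 2 genotypes in the fit and that of AT1G19530 with robust eBayes (adjusted p between 0.0543 and 0.273). The photosynthesis call ended without ago1-27 replicate 2 (adjusted p = 0.131) or se-1 replicate 2 (0.0927), with quantile normalization (0.0573) and with fry (0.0869).

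The mutants were then set beside each other and beside the effect of the transgene. CYP71B22, COR15A, AT3G28500, AT2G43590 and THI2.2 were among 16 probe sets higher in both se-1 and ago1-27, where 0.889 would be shared by chance between comparisons with no array in common. PYK10, GH9B13, GTR2, AT1G10640, AT1G30515, AT1G67860 and AT5G59330 were among 12 lower in both, where 0.501 would be. The mutants had opposite calls at 5 probe sets, with scpl31 higher in se-1 and lower in ago1-27 and AT1G19960 the reverse. Across the 15922 probe sets the effects of se-1 and ago1-27 correlated with r of 0.347, and draws with no change gave 0.485 to 0.515, because both effects use the same Col-0 arrays. The covariance was 0.0415, of which the shared arrays give 0.0273. In draws with no change, the same numbers of probe sets with the smallest p shared 11 to 25 higher and 6 to 20 lower. The observed 16 and 12 lay within these ranges. Those probe sets were taken by p alone, since draws with no change had at most 3 calls in either comparison. The draws therefore cannot tell how many of the 16 and 12 come from the shared arrays.

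Probe sets called in se-1 had values of opposite sign with the transgene in 106 of 118 cases for those higher in se-1 and 45 of 55 for those lower. This pair of effects uses the same se-1 arrays. In draws with no change, the same numbers with the smallest p had opposite signs in 85.6% to 97.5% and 85.5% to 100% of cases. The observed 89.8% and 81.8% were no higher. The correlation, r of -0.504, was also within the range of those draws, -0.516 to -0.482. The covariance, however, was -0.0501, of which the shared arrays give -0.0273. In all, 10 and 9 probe sets were called in opposite directions, where 0.163 and 0.121 would be for comparisons that share no array. The same numbers with the smallest p gave 1 to 10 and 0 to 10 in draws with no change, which reach the observed values. No such draw had more than 3 calls in either comparison. The draws therefore cannot tell how many of the 10 and 9 come from the shared arrays. CYP71B22, COR15A, AT3G28500, AT2G43620 and AT5G05250 were called higher in se-1 than in Col-0 and lower in se-1 p35S::MIR156 than in se-1. ECS1, ZW9, UF3GT, PYK10, AT2G25510, AT2G36885 and AT3G19550 had the reverse calls.

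The effect of ago1-27 and the effect of the transgene in se-1 use no array in common. Of 120 probe sets higher in ago1-27, 86 had negative values with the transgene, and of 145 lower, 121 had positive values. These are 71.7% and 83.4%, against 40.0% to 60.8% and 37.2% to 62.8% in draws with no change. Calls were opposite for 9 and 14 of them, where 0.166 and 0.319 would be by chance and draws with no change gave 0 to 2 and 0 to 4 for the same numbers. They were in the same direction for 1, AT1G43590. The genes with opposite calls included CYP71B22, COR15A and AT3G28500, lower with the transgene, and PYK10, JAL22, JAL33, JAL34 and AT3G02910, higher with it. Across probe sets r was -0.313, against -0.0321 to 0.0194 in draws with no change. Deviations of the real arrays from their genotype means correlated by -0.206 to 0.112 between genotypes, a wider range. The ranges of the draws, also those for the shares and counts above, may therefore be too narrow. CYP71B22, COR15A and AT3G28500 were among 7 probe sets called higher in both mutants and lower with the transgene, and PYK10 was 1 of 2 with the reverse pattern.

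**Figure D3:**
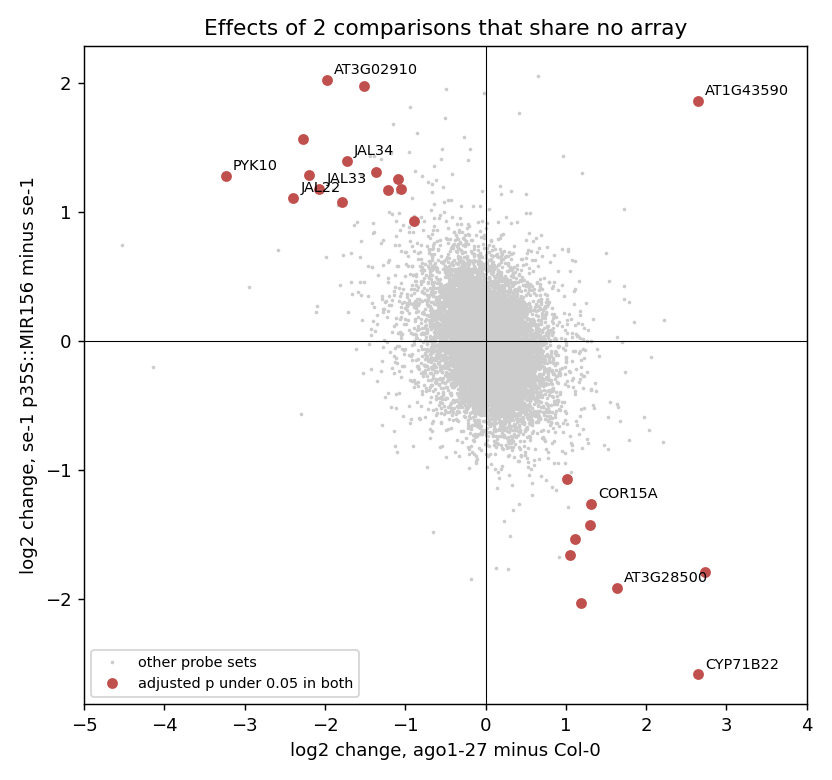
Log2 change of each of the 15922 tested probe sets in ago1-27 relative to Col-0 (horizontal axis) and in se-1 p35S::MIR156 relative to se-1 (vertical axis), with probe sets called in both in red. Of the red points, 14 lie in the upper left, 9 in the lower right and 1, AT1G43590, in the upper right.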

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

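The tests of root tissue in Col-0, of low flavonoid levels on the se-1 arrays and of a sequence difference under the probes were chosen only after the result was seen. The results below stand out because se-1 and ago1-27 changed them by different amounts, as tested by the direct comparison of the mutants, or because a control probe set outside the comparisons differed from Col-0. The direct comparison called 537 probe sets.

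PYK10, a gene of the root marker list (se-1 minus ago1-27, log2 2.15), was lower in ago1-27, as were the lectin genes JAL22 and JAL33, among the largest falls, and JAL34, chosen after its values were seen, while the lectin gene JAL23 had a log2 change of 0.51 (adjusted p = 0.398). The array with the highest background was ago1-27 replicate 2. Without it, the mean log2 change of the 4 lower genes was -2.18 (SE 0.134), against -2.36 (SE 0.159) with all arrays. The fall was thus not confined to that array. The 3 lectin genes were chosen because they fell, and all 4 genes were picked from falls over both ago1-27 arrays. This test could therefore hardly have come out otherwise. Root tissue in the Col-0 samples stays open and cannot be told apart from lower expression in the ago1-27 apex: the median of 17 other root-abundant genes was at most 9.21 on a Col-0 array, below the highest bacterial control signals of 17.1 and 25.6, but 14 of the 17 were too dim to be tested. Of the 3 tested, AT1G62510 (39.6 in Col-0, 3.09 in ago1-27) was called lower and AT1G49570 (38.0 and 13.4) had a value in the same direction, as root tissue in Col-0 would give. HRGP1 (55.8 and 58.2) was not called, and its probe set can detect related transcripts. The mean log2 values of PYK10, JAL22, JAL33 and JAL34 were 8.98 and 8.87 in Col-0 and 6.74 and 6.38 in ago1-27. They were 8.11 and 8.32 in se-1, and 9.52 and 9.40 in se-1 p35S::MIR156. Root tissue in Col-0 alone would not give the difference between the lines with se-1. In se-1 and se-1 p35S::MIR156, mean signals were 22.1 and 26.5 for AT1G62510, 22.8 and 27.7 for AT1G49570, and 44.2 and 43.8 for HRGP1. AT1G62510 and AT1G49570 were near background there, so these values cannot decide on root tissue in those samples, which was not tested.

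Of the 4 flavonoid and anthocyanin genes, 3 rose from se-1 to se-1 p35S::MIR156 (list adjusted p = 1.67e-12, and 0.121 with an estimated correlation), and UF3GT also differed between the mutants (se-1 minus ago1-27, log2 -1.15). Under quantile normalization and median centring the mean log2 change of the list was at least 1.29, against 1.27 without. This test could hardly have come out otherwise, because the arrays were already scaled alike. Over all probe sets the median log2 change was -0.0339, so a difference in scale over whole arrays was too small to give the list mean. Whether the se-1 arrays alone were low cannot be told apart from a rise with the transgene. The mean from Col-0 to se-1 p35S::MIR156 was 0.608 with a SE of 0.26, above 0 but too imprecise to settle it. An effect of miR156 on these genes may contribute and stays open, as does a lower level in se-1.

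AT3G55920 and AT5G59330 were at background in ago1-27 and at least 9.99-fold and 7.62-fold higher in se-1, where the fitted log2 values of 4.06 and 3.46 depend on the pseudocount. AT5G59330 was also called lower in se-1 than in Col-0. A lost chromosome segment would also lower their neighbours, and the 10 nearest measured neighbours of each had median log2 changes of 0.0556 and 0.128 with 0 called by limma (0 and 1 at an unadjusted p under 0.05), which argues against a segment that spans them. A loss of each gene alone was not tested. A sequence difference under the probes may give the same pattern and cannot be told apart from lower expression, since 0 further probe sets of these genes were found. A regulatory effect of ago1-27 on these genes also stays open, as untested.

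The other genes, except AT1G43590, were higher or lower in se-1 than in ago1-27 by the following log2 values. Higher were scpl31 (2.38), AT4G36430 (2.24), ATSBT5.2 (2.09), AT4G18280 (2.03) and AT1G19530 (1.89). AT1G43590 was within background in se-1 and at least 7.90-fold lower there, and its fitted value of -3.14 depends on the pseudocount. Lower were AT5G48490 (-3.09), AT1G19960 (-3.08), AT5G03350 (-2.78), ECS1 (-2.56), AT2G25510 (-2.55), AT5G62360 (-2.54) and AT1G31690 (-1.97). AT5G48490 and AT1G31690 in se-1 and AT4G36430 in ago1-27 had 1 array within background, so their values depend on the pseudocount. From the gene lists, LCR (0.78), ARPN (0.69), COR47 (1.19) and ARR15 (0.97) were higher, and COR15B (-1.60) was lower. The photosynthesis list had a mean of -0.492 (adjusted p = 0.0188, and 0.390 with an estimated correlation), with 0 of 3 genes called by limma over all genes. A control probe set for 5S ribosomal RNA had a mean signal of 84.5 in ago1-27, against 32.9 and 26.4 on the Col-0 arrays, 57.0 and 64.3 in se-1 and 33.1 and 70.5 in se-1 p35S::MIR156.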

How the results depend on the processing

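The replicate block with the se-1 numbers crossed was the only test here chosen after the result was seen. No call of a named gene or gene list changed direction under any alternative run. Quantile normalization, median centring, robust eBayes and the replicate block as numbered left the 5 counts within 1.5 times their values. With no filter on dim probe sets the counts were 68 (se-1 vs Col-0), 98 (ago1-27 vs Col-0), 15 (se-1 p35S::MIR156 vs se-1), 28 (se-1 p35S::MIR156 vs Col-0) and 249 (se-1 vs ago1-27), with 76 of 116 calls of named genes kept and 40 ended. Among named genes, eBayes without trend ended 15 calls and pseudocount 1 ended 8. With the lowest 50% left out, which tests fewer probe sets, 90 of 116 remained. A 2-fold minimum, applied to the counts alone, would end 6 of the named calls. With eBayes without trend the comparisons of se-1 p35S::MIR156 gave 25 (with se-1) and 75 (with Col-0). With only the 2 genotypes in the fit, which leaves fewer arrays, se-1 p35S::MIR156 vs Col-0 gave 280 and se-1 vs ago1-27 gave 263. In the fit of all 8 arrays, a 2-fold minimum left 304 of the 537 of se-1 vs ago1-27. The replicate block gave 187, 271, 59, 143 and 518 in the order above. With the se-1 numbers crossed it gave 323 for se-1 vs Col-0 and 125 for se-1 p35S::MIR156 vs se-1. The deviations of arrays with the same number correlated by -0.206 between Col-0 and se-1 and by 0.112 at most. Arrays with the same number therefore showed at most weak shared deviations. The highest bacterial control, however, was higher on replicate 2 than on replicate 1 in each genotype. It was 17.1 and 25.6 in Col-0, 22.0 and 34.1 in ago1-27, 18.0 and 30.2 in se-1, and 14.2 and 18.3 in se-1 p35S::MIR156. A batch that goes with the numbers therefore stays possible. The correlation of the ago1-27 and MIR156 effects was -0.270 with pseudocount 1, -0.355 with pseudocount 64, -0.229 with no filter and -0.383 with the lowest 50% left out. Gene list shifts numbered 11, and 0 with an estimated inter-gene correlation, while fry ended 5 of them and added 2. The causes of these changes were not tested. Leaving out 1 array gave 32 to 89 for se-1 vs Col-0, 81 to 337 for ago1-27 vs Col-0, 10 to 41 for se-1 p35S::MIR156 vs se-1, 14 to 42 for se-1 p35S::MIR156 vs Col-0 and 257 to 538 for se-1 vs ago1-27. It gave correlations of 0.277 to 0.504 (se-1 and ago1-27), -0.644 to -0.418 (se-1 and MIR156) and -0.315 to -0.242 (ago1-27 and MIR156), 7 to 12 list shifts and 90 to 112 called named genes. Of 116 named calls, 68 held without each array in turn. Genes within the range of the bacterial controls cannot be measured, so their folds are lower bounds.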

Other observations

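The gene families, formed from symbols and annotation, were chosen and tested only after the result was seen, while the test of a segment linked to SE was planned. Among 21 such families, the 11 beta-glucosidase genes (BGLU) had a mean log2 change of -0.44 in se-1 (camera adjusted p = 0.0008, and 0.299 with an estimated correlation) and -0.43 in ago1-27 (adjusted p = 0.00402, and 0.364 with an estimated correlation). BGLU15 fell by 0.88 in se-1, and BGLU46 and BGLU47 fell by 1.46 and 1.11 in ago1-27. PYK10 is a beta-glucosidase outside this family by symbol. The 13 IQD genes, which encode calmodulin-binding proteins, had a mean of 0.36 in ago1-27 (adjusted p = 0.0478, and 0.426 with an estimated correlation), where iqd33 rose by 1.42 and iqd21 by 0.75. Quantile normalization and median centring left the signs of these family means as they were.

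The 67 genes of the organelle genome family were all chloroplast genes. They had a mean of -0.173 in se-1 relative to Col-0 (camera adjusted p = 0.00077, and 0.328 with an estimated correlation). In se-1 p35S::MIR156 relative to se-1 the mean was 0.113 (adjusted p = 0.00925, and 0.727 with an estimated correlation). Of the 67, 0 were called by limma in either, with 11 and 7 at an unadjusted p under 0.05, and the signs were the same under both scalings. As a set, the 82 annotated pseudogenes and transposable elements had camera adjusted p of at least 0.844 in the 5 comparisons. AT1G43590, named above among the largest changes, is 1 of them. It was the only member called in ago1-27 relative to Col-0 and in se-1 p35S::MIR156 relative to se-1, and was higher in each. JAL23, a further lectin gene, rose by 1.08 in se-1 (adjusted p = 0.0475), opposite in sign to the values of JAL22, JAL33 and JAL34 there. GTR2, a glucosinolate transporter gene, had signals of 486 and 382 in Col-0, 200.4 and 194 in ago1-27, 221 and 247 in se-1, and 482 and 395 in se-1 p35S::MIR156.

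A segment linked to SE from another parent of the se-1 line may carry some of the changed genes. Within 100 genes on each side of SE, 1 of 48 tested genes was called in se-1, AT2G27285, where 0.511 were expected. The share was 1.96 times that among genes tested, with a 95% interval of 0.05 to 10.6 and a two-sided Fisher exact p of 0.403. The interval covers both no enrichment and a strong one, so such a segment cannot be told apart from none.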
